A study of Mus musculus with 6 samples.

How the data were processed

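Total RNA from 6 cultures of RAW264.7 cells, 3 with an interfering RNA against Tim-3 and 3 with a control interfering RNA, was labelled with Cy3 and hybridised to 1-colour NimbleGen mouse arrays, per the labels. The authors deposited one table of processed values per array and a table of the series. The deposited values are intensities on a linear scale, made by the authors with RMA per the submitters' processing notes, which name no version and no setting. RMA as commonly defined corrects the background, normalizes probes between arrays by quantiles and summarises the probes of a target; which of these steps were run is not given in the sources used here. Where probes are normalized by quantiles, a shift of all genes in one group is removed. The genome build behind the probes is not given in the sources used here.

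Each array's table held targets identified by sequence accession, and a row for random-sequence probes that was used only as a background level. The deposited series table held 27526 of these targets with the same intensity values (median relative difference 1.7e-07, largest 3.8e-04). All 27526 had an intensity of 100 or more on at least 3 arrays and 0 of the targets outside it did. Columns were matched to samples by the labels. Groups and replicate numbers were taken from the labels, and the files give no slide or scan date.

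Accessions were matched, without versions, to transcripts, symbols and synonyms of a RefSeq gene table for the assembly GRCm38.p6, which was used for names only. Of all targets, 1267 (2.87%) matched 1229 symbols, 912 through a transcript and 355 through a symbol or synonym. The other 42903 are known here by accession alone. The symbol's brightest target over the 6 arrays stood for a gene, and an unmatched accession stood for itself, which gave 44132 genes. The design fixed before the data were examined spoke of named genes. With so few names, the adjustment ran over all 44132 genes, and adjustment over named genes alone was kept as an alternative. Checks of GC content and length were void, since 2.87% of targets matched a gene.

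The intensities were converted to log2 and compared between groups with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, knockdown minus control, no block, no filter on dim targets, Benjamini-Hochberg adjusted p under 0.05, two-sided). The fold screen took genes whose mean log2 values differed by 1 or more. The planned test of gene lists (camera, with fry beside it) required 5 measured members and was not run. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. On simulated data with the spread of these arrays, 44132 genes and 200 changed genes (50 per size), limma recovered 0% of the 1.5-fold, 20% of the 2-fold, 78% of the 4-fold and 84% of the 8-fold changes with 7 false calls, and made 0 calls where no gene was changed.

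The genes named in the text were set by a rule fixed before the data were examined: Havcr2, the 12 largest rises and 12 largest falls among adjusted p under 0.05 with no overlap between groups, a level in the higher group at or above the median of all genes and a proper gene name, and, in each of 30 gene lists, up to 4 members past the test or else the one with the lowest adjusted p. For rises 5 and for falls 7 genes met the rule. Other names, the accessions, and the lists for liver, sex-biased liver genes, brain, striated muscle, testis, skin and hair, kidney, erythroid and interferon-related genes were chosen after the data were seen. One gene of the liver list is not reported here. Alternatives planned beforehand were the replicate number as a block, the series table, quantile normalization and median centring, filters on dim genes, the mean of a gene's targets, trend and robust variance fitting, array weights, an offset of 50, a stricter threshold, a minimum fold and leaving out each array.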

Results

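The study profiled total RNA of RAW264.7 cells, a mouse macrophage-like line, on 1-colour NimbleGen expression arrays. One group of 3 arrays came from cells that stably expressed an interfering RNA against Tim-3, the immune receptor encoded by Havcr2, and the other group of 3 came from cells with a control interfering RNA. Each array is described as a separate culture of drug-selected cells, so the p-values measure the spread between cultures and not that between independently made clones. The arrays carried targets identified by accession, most of them read by 3 probes, and median intensities per array lay between 201.5 and 218.3. Between 26744 and 27376 targets per array had an intensity of 100 or more, while the random-sequence probes averaged 23.1 to 24.5. Havcr2 was not analysed here, so the labels were not checked against the targeted gene. With 3 arrays per group, their number limits the precision.

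The arrays of a group resembled each other except for control replicate 3. Across all targets, which are not independent replicates, Pearson's r of log2 intensities was 0.987 to 0.990 between knockdown arrays and 0.988 between control replicates 1 and 2, against 0.965 to 0.972 between control replicate 3 and each of the others. The first principal component, with 55.5% of the variance, set control replicate 3 apart from the rest, and the second, with 22.4%, placed the 3 knockdown arrays (scores of 17.7 to 19.4) apart from control replicates 1 (-38.7) and 2 (-32.5), with control replicate 3 at 15.9.

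The first comparison asked which genes differed in level between knockdown and control cells. Spire2, an actin nucleator, had the largest rise among the genes with a symbol that passed the test, from a log2 intensity of 7.47 ± 0.24 (SD, n = 3) in control cells to 9.38 ± 0.26 in knockdown cells, a difference of 1.91 (SE 0.19, limma adjusted p = 0.016). Isg15, an interferon-induced ubiquitin-like protein, rose from 7.72 ± 0.09 to 9.14 ± 0.32 (SD, n = 3), a difference of 1.41 (SE 0.18, limma adjusted p = 0.029). Myl6b, a myosin light chain, rose by 1.24 (SE 0.17), Synpo, an actin-associated protein, by 1.18 (SE 0.16), and Speg, a kinase of the myosin light chain kinase family, by 1.15 (SE 0.13), with adjusted p of 0.0355, 0.033 and 0.020. A second target of Speg was higher by 0.89 with an adjusted p of 0.037 over all targets. For Synpo a second, dimmer target differed by only 0.07 with an adjusted p of 0.82, so its rise was seen on 1 of its 2 targets.

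Among the genes that fell, H2bc23, a histone H2B gene, went from a log2 intensity of 8.43 ± 0.10 (SD, n = 3) in control cells to 6.2 ± 0.23 in knockdown cells, a difference of -2.23 (SE 0.15, limma adjusted p = 0.0070). Its intensity was under 100 on all 3 knockdown arrays, and H2B genes share much of their sequence, so probes for it can also read related genes. Odf3l1, related to the outer dense fibre proteins of sperm tails, fell from 11.99 ± 0.04 to 10.26 ± 0.28 (SD, n = 3), a difference of -1.72 (SE 0.16, adjusted p = 0.014). Nbea, a neuronal scaffold protein of membrane traffic, and Kif21a, a kinesin motor protein, differed by -1.06 (SE 0.14) and -1.04 (SE 0.14), with adjusted p of 0.028 and 0.032. Myof, a ferlin that takes part in membrane fusion and repair, differed by -0.92 (SE 0.13, adjusted p = 0.041). Cd300ld5, of the CD300 family of myeloid receptors, differed by -0.78 (SE 0.12, adjusted p = 0.045), and Psd3, an exchange factor for the small GTPase Arf6, by -0.69 (SE 0.10, adjusted p = 0.042). Rad9b, a paralogue of a DNA damage checkpoint protein, was lower by the same test, with a difference of -1.06 (SE 0.15, adjusted p = 0.038). It is named here after its values were seen, since its control mean of 7.47 lay below the median level of all genes, 7.71.

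**Figure D1:**
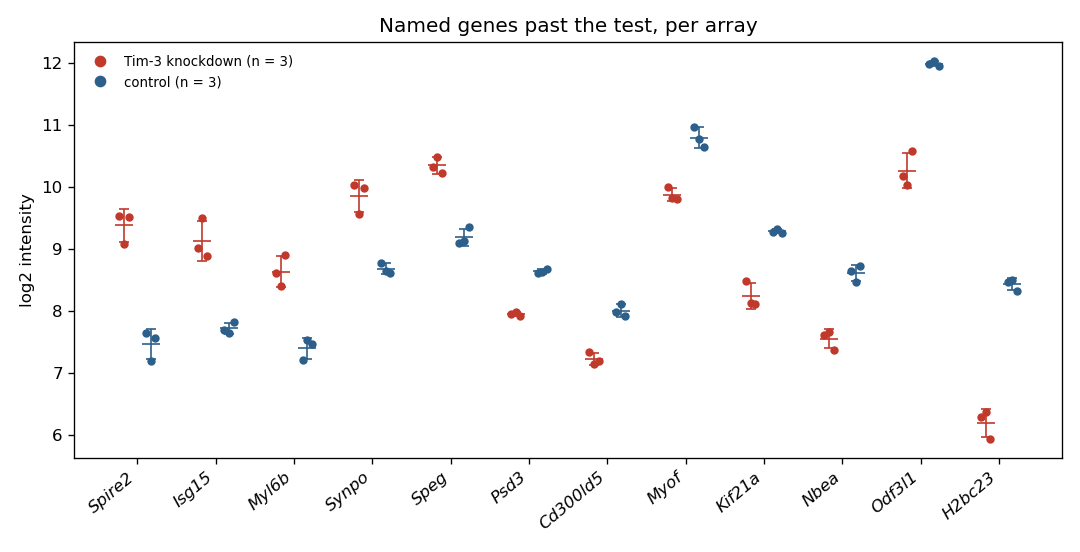
Log2 intensity (vertical axis) of the 12 named genes past the test, in order of their change along the horizontal axis, with 1 point per array, a bar at the mean of each group and error bars of 1 SD (n = 3 per group). The genes were chosen by a rule that required no overlap between the groups, and they run from Spire2, higher by 1.91 in the knockdown, to H2bc23, lower with a difference of -2.23.

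Over the 44132 genes tested, 222 were higher and 313 lower in the knockdown (limma, adjusted p under 0.05). The median size of a called change was 1.16 on the log2 scale, and 167 of the genes that were higher and 203 of those that were lower changed at least 2-fold. Named genes made up 13 of the 535 calls, since 1267 of the targets matched a gene symbol and the others are known here by accession alone. Among the accessions, BC021659 was higher by 3.68 (SE 0.20, adjusted p = 0.0070) and BC024930 by 3.5 (SE 0.24, adjusted p = 0.0070), while AK160604 differed by -3.98 (SE 0.14, adjusted p = 0.0024) and BC042742 by -3.41 (SE 0.22, adjusted p = 0.0070). The groups did not overlap for 25.1% of genes, against 10% by chance. The number of calls depended on every array: it was 1 without knockdown replicate 1, 3 without knockdown replicate 2, 37 without knockdown replicate 3, 57 without control replicate 1, 10 without control replicate 2 and 226 without control replicate 3. Of the 12 named genes, none stayed past the test without knockdown replicate 1 or 2 or control replicate 2, while 2 did without knockdown replicate 3, 1 without control replicate 1 and 4 without control replicate 3, Isg15 not among these (adjusted p = 0.066).

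Restricting the test to the targets that the authors kept in their series table raised the numbers to 739 higher and 1067 lower genes, and 487 of the 535 calls were among them. A variance model with trend and robust fitting called 1092 higher and 1401 lower genes.

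The second comparison applied the screen of the series' design text, a fold of at least 2 between group means with no test. By this screen 705 genes were higher and 547 lower in the knockdown, of which 167 and 203 also passed the test. The screen moved with the control arrays. Without control replicate 3, 474 genes were at least 2-fold higher and 529 lower, against 1122 and 807 without control replicate 1 and 1038 and 851 without control replicate 2. Of the 705 genes at least 2-fold higher, 249 (35.3%) were at least 4-fold lower on control replicate 3 than on each of the other 5 arrays.

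**Figure D2:**
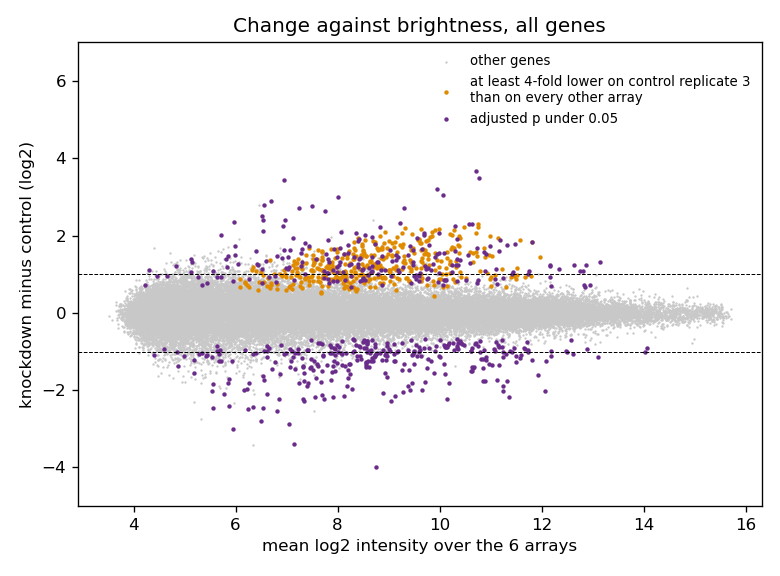
Difference between knockdown and control means (log2, vertical axis) against mean log2 intensity over the 6 arrays (horizontal axis), with 1 point per gene for 44132 genes and dashed lines at 2-fold. Purple points passed the test (222 higher, 313 lower), and orange points, 389 genes at least 4-fold lower on control replicate 3 than on every other array, lie above 0.

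Genes made mainly by hepatocytes were among those low on control replicate 3 alone. Hpn, a hepatocyte serine protease, had a mean log2 intensity of 11.25 ± 0.24 (SD) over the other 5 arrays and 5.26 on control replicate 3. Kng1, a plasma kininogen precursor, had 9.79 ± 0.27 and 4.51, and Pklr, the liver and red cell pyruvate kinase, 10.00 ± 0.32 and 5.87. A liver list, written after the data were seen, held 15 genes with an intensity of 100 or more on some array, of which 10 had been picked because they showed this pattern. Of the 5 others, 3 were lowest on control replicate 3.

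**Figure D3:**
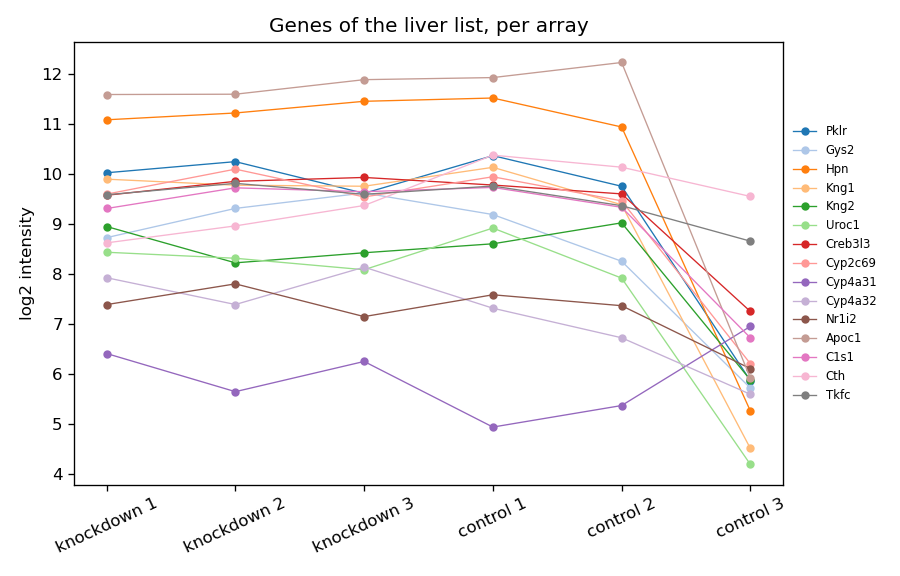
Log2 intensity (vertical axis) of 15 genes of the liver list on each of the 6 arrays (horizontal axis), with lines joining the values of one gene. Of these, 10 were picked for being low on control replicate 3 and 3 of the other 5 are also lowest there. Hpn has 5.26 there against a mean of 11.25 on the other 5 arrays, and Cth and Cyp4a31 are not lowest there.

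The third comparison concerned 30 gene lists on macrophage function, interference and RNA quality, fixed before the data were examined. Of their members 19 were measured under a symbol, spread over 15 lists with at most 2 in each, and no list reached the 5 members set for a list test, so no list was tested as a group. Of the 19 genes, 1 rose (Isg15) and 18 did not pass the test over all genes. Both measured members of the interferon-stimulated list, Isg15 and Parp9, were higher when adjusted over these 2 genes alone (limma adjusted p 4.1e-04 and 0.035). Adjusted likewise over the 2 measured antigen presentation genes, Nlrc5, the transactivator of MHC class I genes, was higher as well (adjusted p = 0.031). Parp9 differed by 0.31 and Nlrc5 by 0.40, with adjusted p of 0.26 and 0.18 over all genes. Adjustment over 2 genes hardly raises a p-value, and 7486 of the 44132 genes had an unadjusted limma p under 0.05. Values like those of Parp9 and Nlrc5 were therefore common on these arrays. Tapbpl, the other antigen presentation gene, differed by -0.02.

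The other lists were each read by 1 or 2 genes, given here as knockdown minus control on the log2 scale, for all but 2 of them with the 95% interval of limma. Rpl12, a ribosomal protein, differed by 0.00 (95% interval -0.29 to 0.30), Hmgcs1, an enzyme of cholesterol synthesis, by -0.03 (-0.28 to 0.22), and Keap1, the repressor of NRF2, by -0.01 (-0.30 to 0.27). Ptprc, the leukocyte antigen CD45 and the only measured macrophage identity gene of 36 listed, differed by -0.17 (-0.61 to 0.26). Its mean log2 intensities, 7.24 in knockdown and 7.42 in control cells, lay below the median level of all genes, 7.71. Acp5, the tartrate-resistant phosphatase of osteoclasts, differed by -0.27 (-0.67 to 0.13), and Tfe3, a regulator of lysosomal genes, by 0.36 (-0.0017 to 0.73). Cdkn1a, the p53 target p21, differed by 0.08 (-0.28 to 0.45), Uhrf1, a factor of DNA replication and methylation, by 0.13 (-0.28 to 0.55), Vegfa by -0.06 (-0.52 to 0.39), and the phosphatase gene Dusp5 by -0.03 (-0.59 to 0.53). The erythroid enzyme Alas2 and the epithelial splicing factor Esrp1 differed by 0.26 (-0.71 to 1.23) and 0.13 (-0.52 to 0.78). Apoc1, an apolipoprotein of hepatocytes and macrophages, differed by 1.67 (-2.33 to 5.66), with a log2 intensity of 5.92 on control replicate 3 and a mean of 11.85 on the other arrays, and by -0.39 without that array. Of the same lists, Siglec15, a second osteoclast gene, differed by 0.19 (adjusted p = 0.57) and Lipa, a lysosomal lipase, by -0.01 (adjusted p = 0.97). None of these 15 genes passed the test, which does not show that their levels were alike.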

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

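The settings were planned before the data were examined, except adjustment over named genes alone and leaving out targets low on control replicate 3, which were chosen after the data were seen. The counts of 222 higher and 313 lower genes stayed within 1.5 times under quantile normalization, median centring, the mean of a gene's targets, array weights and without the targets low on control replicate 3 alone. Higher and lower counts were 739 and 1067 in the series table, 484 and 693 without the dimmest 25% of genes, 947 and 1242 without genes below the median level, 584 and 832 with log2(value + 50), and 1092 and 1401 with trend and robust fitting. They were 30 and 30 at an adjusted p under 0.01 and 25 and 24 with a minimum fold of 1.5. Adjusted over named genes alone they were 5 and 8, the same 13 named genes that were called over all genes, so on these genes the calls did not move. Leaving out one array gave 0 to 117 higher and 1 to 109 lower genes. The cause was not tested, except that fewer genes or arrays are tested or a stricter limit is set by construction.

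Of the screen for 2-fold changes, 705 higher and 547 lower genes became 381 and 163 without genes below the median level and 300 and 181 with log2(value + 50). In the series table the lower genes numbered 287, and without the targets low on control replicate 3 alone the higher genes numbered 456, a fall set by construction, since these targets were picked for being low on a control array. Leaving out one array gave 474 to 1122 higher and 529 to 851 lower genes, where 1122 was without control replicate 1 and 851 without control replicate 2.

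With the replicate number as a block, limma called 0 higher and 0 lower genes, with 3198 and 3335 at an unadjusted p under 0.05. Deviations of same-numbered arrays from their group means correlated at -0.03, -0.01 and 0.00 over all targets, so no pairing by number was seen. Large deviations of single arrays can hide a weaker shared part. The files give no slide or scan date, so a pairing was not excluded.

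For single genes, 86 of 218 results for the called genes lost significance, 0 changed direction, and 1 of 235 results for the others passed the test. The 12 named genes passed in 9 to 12 of their alternatives, with adjusted p up to 0.20. Random-sequence probes at an intensity of 23.1 to 24.5 set the background, and each filter that removed dim genes raised the counts of calls. Havcr2 was not analysed here, and the list tests were not run because no list had 5 members measured.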

Other observations

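The test on the authors' filtered table was chosen before the data were examined, and the tests on the splits, control replicate 3, the fold screen and Isg15 were chosen after the result was seen. In the authors' filtered table, where the test ran on fewer dim targets, 46 of 692 named genes passed limma's test (18 higher and 28 lower). Of all 27503 genes there 1806 passed, a similar share, so the named genes did not stand out. Of the 46, 33 were in addition to those named above, and the following were picked after their values were seen. Dab2, an endocytic adaptor, was higher in the knockdown by 0.81 (10.69 ± 0.18 against 9.87 ± 0.26, SD, n = 3, adjusted p = 0.034). Zc3h12a, the ribonuclease Regnase-1 that degrades inflammatory transcripts, was higher by 0.55 (adjusted p = 0.0175). Gas7, a protein of the actin cytoskeleton, differed by -0.70 (12.59 ± 0.14 against 13.30 ± 0.06, SD, n = 3, adjusted p = 0.015), and Raph1, also known as lamellipodin, by -1.17 (adjusted p = 0.034). Steap3, a ferrireductase of iron uptake, differed by -0.56 (adjusted p = 0.022), and the imprinted noncoding RNAs Airn and Peg13 by -0.65 and -0.60 (adjusted p of 0.030 and 0.015). With all 44132 genes tested their adjusted p lay between 0.061 for Gas7 and 0.10 for Dab2, so none of these 7 genes passed there.

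Of the 10 splits of the 6 arrays into 3 and 3, 1 (the real one) gave as many as 535 called genes, and the highest of the others gave 0. For genes at least 2-fold apart, 1 split, again the real one, reached 1252, and the highest of the others gave 664. With 10 splits no share under 0.05 can be had.

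Listed liver genes were among the targets at least 4-fold lower on control replicate 3 than on every other array (389 genes), while 78 targets were at least 4-fold higher there and no other array had a target that far below the rest. Targets as bright on the other 5 arrays (8070) had a median difference of 0.0024 there, so such targets were not low in general. Where probes are normalized by quantiles a shared shift is removed, so a fault in that array's background or normalization stays open. Of 226 genes called without control replicate 3, 93.8% lay nearer to the other controls than to the knockdown on that array. These genes were called between the knockdown and control replicates 1 and 2. They cannot tell another line without the knockdown from a control culture. They argue against a knockdown culture under that label, although the second principal component placed the array at 15.9, near the knockdown arrays. A candidate explanation is liver RNA on the other 5 arrays: of 5 listed liver genes that had not been picked for the pattern, 60% were lowest on control replicate 3, against 19.4% of 36 genes of 6 other tissue lists, too few genes to decide. The list was settled after these values were seen, and Slc2a9, a urate transporter of liver and kidney, was looked at with them and then put in the kidney list, where it is 1 of the 36 genes and not lowest on control replicate 3. With it on the liver side the shares are 50% of 6 genes and 20% of 35. No biological explanation was tested, and whether the cultures made these transcripts themselves stays open.

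By list, the genes lowest on control replicate 3 were 1 of 9 for brain, 1 of 7 for striated muscle, 3 of 6 for testis, 0 of 4 for skin and hair, 1 of 5 for kidney, 1 of 5 for erythroid, 1 of 6 for interferon-related, 2 of 3 for female-biased liver and 2 of 2 for male-biased liver genes, counting genes with an intensity of 100 or more on some array. Cyp3a41b and Cyp4a12a, of the last 2 lists, had been seen to be low there before they were listed. These counts do not give levels. Hba-a2, of the erythroid list, had a mean log2 intensity of 11.83 on the other 5 arrays and 11.94 on control replicate 3. Spo11, of the testis list, had 10.25 and 10.59. Hba-a2 and Spo11 were picked after their values were seen. The brightest genes reported from the liver list, Apoc1 and Hpn, had mean log2 intensities of 11.85 and 11.25 on the other 5 arrays, and at least Apoc1, Cth and Tkfc, 3 genes of the list, are also expressed by other cell types. Liver genes that differ between the sexes of mice were compared between arrays of a group picked after the values were seen. Sult2a1 and Sult2a2, higher in female liver, were higher on knockdown replicate 1 than on the mean of knockdown replicates 2 and 3 by 2.81 and 2.62, and on control replicate 2 than on control replicate 1 by 4.88 and 3.63. Cyp4a12a, higher in male liver, differed by -2.55 and -2.58 in these comparisons. Cyp3a41b, also a gene of female liver, gave -0.62 and 0.95, and Cyp4a12b, of male liver, -0.09 and -0.97. On all 6 arrays 2 targets of Xist, the RNA that coats the inactive X chromosome of female cells, had log2 intensities between 10.50 and 12.03. Random-sequence probes lay between 4.53 and 4.62. Whether this Xist signal came from the cultured line itself was not tested.

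More genes were at least 2-fold higher than lower by fold alone (705 and 547, a ratio of 1.29). Dim targets are argued against as the source, since the ratio was 1.86 in the authors' filtered table. Control replicate 3 is a candidate source: without it the ratio was 0.90, while leaving out any one of the other 5 arrays kept it between 1.22 and 1.39.

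Isg15 was higher in the knockdown. Isg15 on control replicate 3 lay 0.16 from the mean of the other controls, against a change of 1.41. Its level on the controls did not follow the liver genes. Liver RNA on the knockdown arrays was not tested as a source, since the controls cannot show what such RNA would add there. A wider interferon response in the knockdown may go with the rise of Isg15. Of the 4 other interferon-related genes with an intensity of 100 or more on at least 3 arrays, 0 passed the test over all genes. These were Parp9, Nlrc5, Ifit3b and Irgm2. Their changes were 0.31, 0.40, 0.34 and -0.04, and the upper 95% limits of 0.59, 0.70, 0.87 and 0.45 leave a modest rise open for each of them.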
